A study of Mus musculus with 8 samples.

How the data were processed

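RNA of whole mouse liver and of sorted liver cells was measured on 8 Affymetrix mouse expression arrays, 1 per group: whole liver of a wild-type mouse, HSC, VitA-GFP+ cells and MC with no injury named in the labels, PF after sham surgery, and HSC, PF and MC of biliary fibrosis. The sorted cells came from Col1a1-GFP reporter mice. Vitamin A, GFP and GPM6A served as sort criteria, and the labels name no gate for PF. RNA was amplified from small amounts before labelling.

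The deposited intensity values were normalized by the authors with RMA in Partek, per the submitters' processing notes, with versions not given in the sources used here. They are on the linear scale, array medians running from 39.62 to 51.22 over non-control probe sets. The design had assumed log2 values, so log2 was taken here first. The 2 deposited tables hold the same values (largest difference 0), so results from the other table were not computed. Whether RMA ran on all 8 arrays together is not given in the sources used here.

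Of 45101 probe sets, 64 are controls, 38011 name 1 gene, 1280 name several and 5746 name none. Symbols were brought up to date through gene identifiers for 35012 probe sets, which altered 3174. Each of 20677 genes was represented by the probe set with the highest mean over all arrays, chosen among several for 9608 genes. No coordinates were used.

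A gene was called higher or lower when its log2 difference was at least 2 (4-fold) and the higher array was at or above its own median of non-control probe sets. For a fraction against both others, the difference is from the higher of the other two arrays. HSC and MC of biliary fibrosis have no sham array of their own fraction and were set against the array of the same fraction with no stated injury. These pairs cross 2 series of sample codes, the VitA-GFP+ array carries a code of another series still, and whether the codes mark separate rounds of arrays is not given in the sources used here. With 1 array per group there is no p value, error or count of significant genes, and the spread between probe sets of a gene describes the measurement only. For each of 23 gene lists the median difference was given as a percentile among 10000 random lists of the same size, drawn in 20 bins of mean level, and percentiles under 2.5 or over 97.5 count as outside the range of random lists. Members of a list vary together more than random genes, so these percentiles are no test.

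The groups, comparisons, gene lists, size rule, most of the other settings tried and the rule for named genes were fixed before the data were examined. The rule takes the 8 largest differences per fraction with no stated injury and per direction in the 3 fibrosis pairs, and the 5 largest elsewhere, leaving out predicted genes. Examples of a list are among its 4 members with the largest absolute difference. Gpm6a, Col1a1, Lrat, Acta2, Thy1, Entpd2, Msln and Wt1 are given for the 3 fibrosis pairs, and elsewhere only where another rule picks them. The range over probe sets is given where those of a named gene at the minimum level lie over 3 apart or go both ways, a rule set after the values were seen. Other list members are named where a sentence lists genes shared between pairs.

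The steps were tested on simulated data made from the sham PF array, after the first run on the real arrays. Noise added to that array stood in for PF of biliary fibrosis. With noise of SD 0.4, 1 of 335 genes with a true difference of 1 was called, against 334 of 335 at a true difference of 3 and 330 of 330 at 4, and 0 of 102385 unchanged genes. The altered genes were drawn from bright genes, which is favourable for the rule. The cut of 2 lies far above this noise, so the absence of calls among unchanged genes followed from the setting. The median SD between probe sets of a gene was 0.393 in the PF pair, but 0.666 in the HSC pair and 0.935 in the MC pair, which were not simulated. Of 100 random lists of 25 genes, 6 fell outside the range with no shift and 100 with a shift of 1.

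Settings chosen beforehand and tried 1 at a time were quantile normalization anew, a shift of each array to the same median, no minimum level, the 75th percentile as minimum level, the mean of a gene's probe sets, only probe sets without suffixes that mark matches to several transcripts, a 2-fold rule, and, for HSC and MC of biliary fibrosis, subtraction of the difference between sham PF and VitA-GFP+ cells. Settings chosen after seeing the data left out genes 2-fold apart between those 2 arrays, or swapped sham PF and VitA-GFP+ cells. A list median or gene counts as moved at over 0.5, a bound also chosen after seeing the data. Probe sets that name no gene or several were left out of the gene counts. R 4.3.3 with limma 3.58.1 did the quantile normalization, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 the rest.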

Results

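Collagen-reporter cells of mouse liver were profiled as hepatic stellate cells (HSC), vitamin A-negative and GFP-positive cells (VitA-GFP+ cells), portal fibroblasts (PF) and mesothelial cells (MC), without stated injury, after sham surgery or in biliary fibrosis. Each of the 8 groups is 1 array, so there are no replicates, no test was run, and every difference is a difference between single arrays. Differences are on the log2 scale. A gene counts as 4-fold higher or lower when the difference reaches 2 and the higher array is at or above its own median. List medians are set against 10000 random lists of the same size matched on level, and their percentile describes these arrays only.

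HSC and MC with no stated injury carried marker genes of their names, and the 3 fractions differed in the markers of other cell types seen beside them. HSC had 211 genes at least 4-fold higher than in both VitA-GFP+ cells and MC. Among 30 measured HSC markers, 17 were in this group, with a median difference of 2.40 (percentile 100): Colec10 (5.88), Angptl6 (5.74), Vipr1 (5.70) and Hhip (5.50) differed most. Tlcd4 (5.90), Ptger2 (5.72), Disp2 (5.71), Lama1 (5.62) and the carotenoid-cleaving enzyme Bco1 (5.56) also stood out. Lrat, which esterifies retinol for storage, was higher by 4.17, while the retinoid list as a whole, led by Aldh1a2 (-6.39) and Cyp26b1 (-6.33), had a median of 0.01 (percentile 97.4, 2 of 22 higher). Portal fibroblast markers were lower in HSC, with a median of -5.68 from the higher of the other two arrays (percentile 0, 0 of 24 higher) and Mgp (-10.44) and Gas6 (-9.07, probe sets -9.07 to -3.55) as the largest differences. Vitamin A and GFP were part of the sort, so the placement of vitamin A genes is partly set by the gate.

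VitA-GFP+ cells had the most distinctive genes, 651 against 211 in HSC and 193 in MC. The smooth muscle actin Actg2 (9.15), Dpep1 (8.24), Gpihbp1 (7.65), Tnnt2 (7.42), Itih5 (7.38, probe sets 3.70 to 7.38), Ankrd1 (7.20) and Spp1 (7.16) led. Ighg (8.40) belongs to a family of near-identical immunoglobulin genes, so which copy was measured is uncertain. Portal fibroblast markers were higher by a median of 0.35 (percentile 99.9, 5 of 24 higher), with the matrix genes Dpt (6.64), Mfap4 (6.40) and Col15a1 (5.32) and the peptidase inhibitor Pi16 (4.25). Markers of other cell types were higher in the same array by more: endothelial 3.84 (16 of 20, Dnase1l3 6.44, Oit3 6.03), Kupffer cell and macrophage 3.65 (13 of 18, C1qb 5.21, Lyz2 5.21), lymphocyte, natural killer and neutrophil 2.26 (11 of 21, Ptprc 6.23, probe sets -0.12 to 6.23), and smooth muscle and pericyte 2.07 (11 of 19, Cnn1 6.09). Each of these 4 medians was at percentile 100. Mesothelial markers had a median of -1.22 (percentile 0, 2 of 29 higher: Cdh1 5.32, Dsp 2.58), but here MC is 1 of the arrays set against. Their median level was 4.97 above the array median in VitA-GFP+ cells, against 6.49 in MC and -1.40 in HSC, so this array carried mesothelial genes too. With the 75th percentile of each array as minimum level, the count was 369.

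MC had 193 genes higher than in both other fractions. Mesothelial markers were higher by a median of 1.17 (percentile 100, 10 of 29 higher), among them Krt7 (2.51) and mesothelin, Msln (2.46). The junction genes Cdh1 (-5.32) and Dsp (-2.58) on the same list were lower than in the higher of the other two arrays. Highest in MC were Xist (6.94), Trim66 (4.65), Lrrc31 (4.003), the carbonic anhydrase Car3 (3.57), the transporters Slc4a11 (3.54) and Slc26a3 (3.53), Grip1 (3.31) and Fam184a (3.30). Epithelial junctions and keratins had a median of -0.50 (percentile 20.7, 2 of 26 higher). With sham PF in place of VitA-GFP+ cells, 397 genes were higher in MC, of which 165 were shared with the 193. The GPM6A protein was the sort marker of MC.

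Against the same whole-liver array, 1767 genes were higher and 2282 lower in HSC, 2162 and 1501 in VitA-GFP+ cells, and 1816 and 2355 in MC. The share of higher genes in VitA-GFP+ cells was 59.0%, and 47.0% after each array was shifted to the same median. HSC markers were higher in HSC by a median of 4.62 (29 of 30), portal fibroblast markers in VitA-GFP+ cells by 4.34 (21 of 24) and mesothelial markers in MC by 6.84 (22 of 29), each at percentile 100. Hepatocyte markers differed by a median of -6.21 in HSC, -5.97 in VitA-GFP+ cells and -9.18 in MC (percentile 0 in each). Fibrillar collagens and matrix cross-linking genes were higher by 3.51, 4.16 and 2.79 in the same order (percentile 100). Immediate early genes were also higher than in whole liver in all 3 fractions, with medians of 3.35, 4.29 and 3.34 (percentile 100, 21, 22 and 18 of 26 higher). The stress-responsive Nr4a1 (8.38 in HSC, 9.08 in VitA-GFP+ cells), Fosb (8.36 and 8.70) and the heat shock gene Hspa1a (7.50 in HSC) were among the 5 highest differences, as were the Y-linked Ddx3y (8.96 in HSC, probe sets 5.24 to 8.96, and 8.44 in VitA-GFP+ cells, 4.91 to 8.44) and Eif2s3y (8.46 in HSC). VitA-GFP+ cells added Ankrd1 (8.31) and Tnnt2 (8.13). In MC the highest were Chst4 (9.23), Bnc1 (9.02), Spock2 (9.01, probe sets 2.14 to 9.01), Upk1b (8.96) and Rspo1 (8.60).

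The map of median list levels on each array shows these cell identities side by side, in log2 units above the median of the array (red above, blue below). HSC markers stand highest in the 2 HSC arrays, mesothelial markers in the 2 MC arrays, and portal fibroblast markers in the 2 PF arrays and the VitA-GFP+ array. Cholangiocyte markers are highest in PF of biliary fibrosis.

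**Figure D1:**
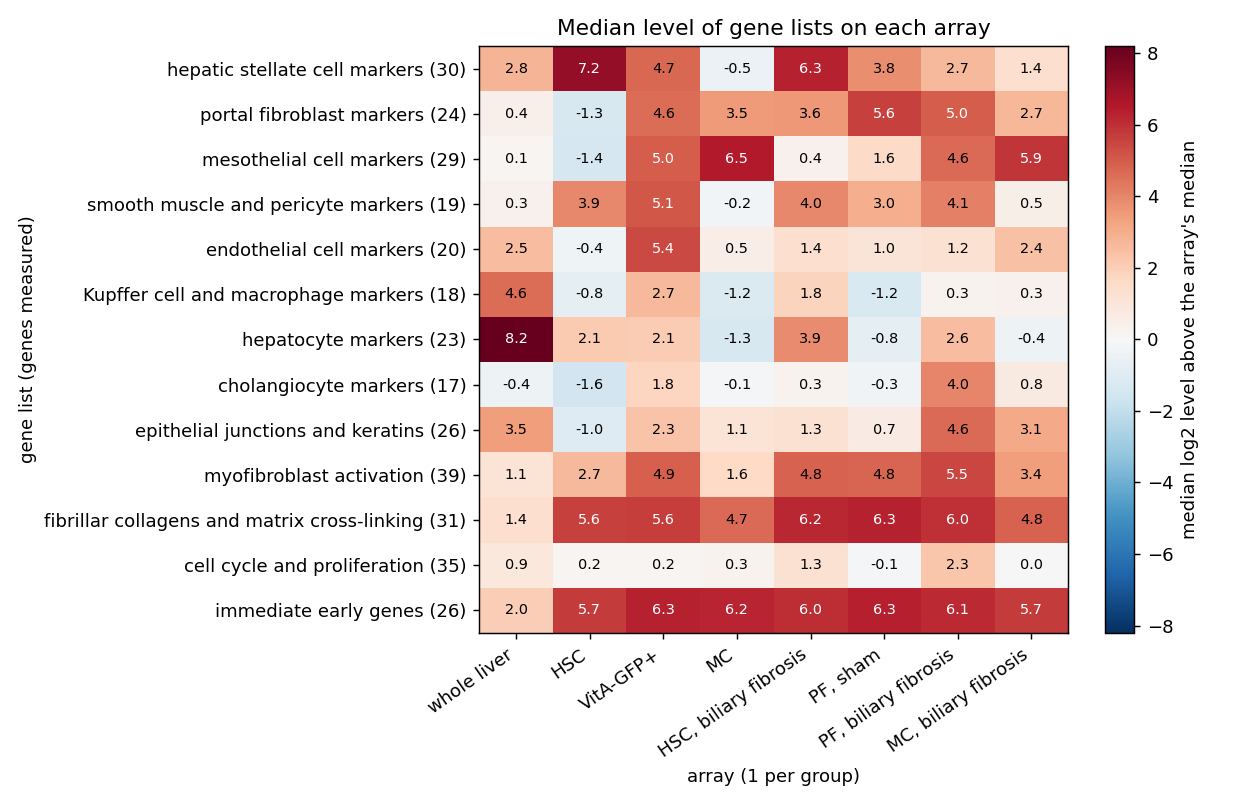
Median level of 13 gene lists on each of the 8 arrays, as log2 units above the median of the array. Red is above and blue below that median, the number in each cell is the value, and the number of measured genes stands after each list name. Each column is a single array.

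PF of biliary fibrosis showed genes of bile duct epithelium, hepatocytes and dividing cells at far higher levels than sham PF, with fibrillar collagens little apart. In all, 779 genes were 4-fold higher and 326 lower. Cholangiocyte markers were higher by a median of 3.90 (percentile 100, 11 of 17 higher), led by the claudin Cldn7 (5.89), the chloride channel Cftr (5.64) and the transcription factor Ehf (5.40). Epithelial junctions and keratins were higher by 3.72 (percentile 100, 20 of 26), including the splicing regulator Esrp1 (5.54), the keratin Krt18 (5.51) and desmoplakin, Dsp (5.51). Hepatocyte markers were higher by 2.94 (percentile 100, 14 of 23 higher, 1 lower), including Serpina1c (6.96), the vitamin D carrier Gc (6.89) and the fibrinogen chain Fga (4.79). Hnf4a, a hepatocyte transcription factor, differed by 7.21, with probe sets from 2.89 to 7.21 and a value of -0.01 from its probe sets that match 1 transcript only. Mesothelial markers had a median of 1.91 (percentile 100, 14 of 29), with Krt18, Dsp, Cdh1 (5.07) and Krt8 (4.57) at the top, which are also epithelial genes. Only 7 of the 29 are on another list, so shared genes do not make up all 14. Of the 779 higher genes, 207 were 4-fold lower in sham PF than in VitA-GFP+ cells, and 111 of the 326 lower genes were 4-fold higher. Both pairs share the sham PF array, so its own level enters each. Median levels above the array median in VitA-GFP+ cells, sham PF and PF of biliary fibrosis were 2.08, -0.75 and 2.56 for hepatocyte markers. They were 1.75, -0.32 and 4.01 for cholangiocyte markers, and 0.18, -0.11 and 2.28 for proliferation genes.

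Proliferation genes were higher in PF of biliary fibrosis by a median of 1.94 (percentile 100, 15 of 35 higher, 0 lower), with Mki67 (4.60), the topoisomerase Top2a (4.42), Cdca8 (4.38) and Cenpf (4.34). The median was 1.30 when a gene's probe sets were averaged. Macrophage markers were higher by 1.69 (percentile 100, 7 of 18, C1qb 5.20, Csf1r 4.54, Tyrobp 3.67, Ctss 3.65) and lymphocyte, natural killer and neutrophil markers by 0.50 (percentile 99.4, 2 of 21, Coro1a 2.20, Cd52 2.05). Myofibroblast activation genes were higher by 0.47 (percentile 100, 4 of 39 higher, 1 lower): osteopontin, Spp1 (5.05), Col8a1 (2.67) and S100a4 (2.08) against Islr (-2.54). Smooth muscle and pericyte markers were higher by 0.66 (percentile 99.8, 3 of 19: Rgs4 4.08, Actg2 2.34, Cspg4 2.12). Fibrillar collagens and cross-linking genes had a median of -0.17 (percentile 18.6), and 0 of 31 met the 4-fold rule, with Col12a1 at 1.94 and Dcn at -1.67.

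HSC and portal fibroblast markers had medians below those of random lists in the same pair, with few members past the 4-fold rule. HSC markers had a median of -0.90 (percentile 0, 4 of 30 lower, 2 higher, Lrat -3.06, Hhip -2.95, Ifitm1 -2.41, Ngfr -2.31) and portal fibroblast markers of -0.82 (percentile 0, 2 of 24 lower: Clec3b -3.18 and Fbln1 -2.34, with Ptgds at 2.96). Interferon response genes had a median of -0.60 (percentile 0.05, 0 of 23 4-fold), regulators of epithelial-mesenchymal transition of -0.45 (percentile 0.81, Tcf21 -2.94, Cdh2 2.04), retinoid genes of -0.40 (percentile 1.05, Cyp26a1 4.47, Plin5 2.16) and immediate early genes of -0.33 (percentile 2.07, Klf2 -1.88). Chemokines and cytokines had a median of -0.05 (percentile 42.2) although Lcn2 (6.83), Saa3 (5.78), Il1rn (5.55) and Cxcl9 (3.12) were all higher. Medians of the other lists were 0.05 for basement membrane (percentile 68.6, Lama5 2.53, Col4a4 -2.48), -0.02 for endothelial markers (percentile 41.5, Esam 2.84, Dnase1l3 -2.39), -0.09 for proteases and inhibitors (percentile 37.6, Adamts5 -2.41), 0.15 for glycolysis and hypoxia (percentile 87.3, Car9 3.41) and 0.16 for cholesterol and fatty acid synthesis (percentile 83.6).

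By size, the highest differences in PF were Ddx3y (9.06, probe sets 3.94 to 9.06), the matrix protease Mmp7 (7.51), the lipoprotein Apob (7.49), Hnf4a, Serpina1c, Gc, the biliary transcription factor Onecut2 (6.88, probe sets 3.68 to 6.88) and Lcn2. At the other end were Xist (-6.66), Pcdh8 (-5.59), Negr1 (-5.57), Mapk10 (-4.87), Slc36a2 (-4.84), Pm20d1 (-4.79, 0.98 from its other probe sets), Foxl2os (-4.70) and Arhgap20 (-4.64). Ddx3y, Eif2s3y (6.43) and Kdm5d (4.32) are Y-linked and Xist marks an inactive X: the sex-linked list had a median of 4.32 (percentile 100, 4 of 5 higher, 1 lower). Sham PF had Xist at 11.96 and Ddx3y at 2.78, while PF of biliary fibrosis had them at 5.31 and 11.83. With VitA-GFP+ cells in place of sham PF, 810 genes were lower in PF of biliary fibrosis, of which 104 were shared with the 326.

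HSC of biliary fibrosis, set against HSC with no stated injury, showed 1220 genes higher and 648 lower. This pair crosses 3'/5' ratios of Gapdh of 1.75 and 5.68, and without genes 2-fold apart between sham PF and VitA-GFP+ cells the counts were 550 and 396. Portal fibroblast markers were higher by a median of 2.44 (percentile 100, 13 of 24 higher, 0 lower), with the matrix Gla protein Mgp (8.30), Cd34 (7.46), Col15a1 (6.70) and Gas6 (5.81). Myofibroblast activation genes were higher by 1.19 (percentile 100, 14 of 39, 0 lower), with Spp1 (8.07), Ltbp2 (7.54), S100a4 (6.47) and S100a6 (6.38). Proteases and inhibitors were higher by 1.70 (percentile 100, 11 of 24, Plat 5.46, Mmp10 5.08, Timp1 4.88) and fibrillar collagens and cross-linking genes by 0.85 (percentile 100, 7 of 31), with lysyl oxidase, Lox (6.10), Col12a1 (5.88), Fmod (5.32) and elastin, Eln (3.62, probe sets 0.34 to 3.62). Basement membrane genes were higher by 1.02 (percentile 100, 7 of 21, Col4a5 5.62). Col1a1 itself differed by 1.78, Acta2 by 4.34 and Thy1 by 4.58.

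Some inflammatory and growth genes were higher in the same HSC pair. Chemokines and cytokines had a median of 0.77 (percentile 99.9, 10 of 28 higher, 1 lower), with Lcn2 (7.57) and the interleukin 6 family members Il6 (6.27) and Lif (5.76). Proliferation genes had one of 0.98 (percentile 99.8, 10 of 35 higher, 1 lower, Rrm2 4.13), cholesterol and fatty acid synthesis 0.96 (percentile 99.6, Fdft1 4.53), glycolysis and hypoxia 0.64 (percentile 99.2, the hexokinase Hk2 5.42) and regulators of epithelial-mesenchymal transition 0.46 (percentile 97.6, Prrx1 5.11, probe sets 1.47 to 5.11, Foxc2 4.73). HSC markers had a median of -0.56 (percentile 0.07, 2 of 30 lower: Vipr1 -2.51 and Ntn1 -2.03, against Alcam at 2.01), and Lrat differed by -0.58. With the difference between sham PF and VitA-GFP+ cells subtracted, the median of HSC markers was 0.17 and Xaf1 was at 0.105, and medians came down to 0.21 for collagens, 0.97 for proteases and 0.13 for chemokines and cytokines. The median level of HSC markers was 3.84 in sham PF and 4.69 in VitA-GFP+ cells, so they rise by construction. Lrat (-2.40 between those 2 arrays) changed sign, and Rrm2 (2.86) no longer met the 4-fold rule. Interferon response genes had a median of -0.78 (-0.18 after the same subtraction, percentile 0.01, Psmb9 -2.70, Ifit3 -2.22, Xaf1 -2.16). Retinoid genes had a median of 0.17 (percentile 63.4), though the retinoic acid-making Aldh1a2 (5.35) and the retinoic acid-degrading Cyp26b1 (3.13) were both higher.

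Markers of other cells were higher in HSC of biliary fibrosis too. Macrophage markers had a median of 3.28 (12 of 18, Csf1r 7.66, probe sets 3.06 to 7.66, C1qb 6.05, Ctss 5.44), hepatocyte markers of 2.05 (13 of 23, Hnf4a 3.93 but -0.11 without probe sets that match several transcripts, Pck1 3.85), epithelial junctions and keratins of 1.40 (10 of 26 higher, 1 lower, Krt18 6.61, Krt8 6.59), cholangiocyte markers of 1.14 (8 of 17, Sox9 5.20), lymphocyte, natural killer and neutrophil markers of 1.07 (7 of 21, Ptprc 7.20, probe sets -1.69 to 7.20) and mesothelial markers of 0.995 (12 of 29, Pdpn 6.44), each at percentile 99.9 or above. Smooth muscle (0.19, percentile 70.6), endothelial (0.46, percentile 87.4), immediate early (-0.07, percentile 30.7) and sex-linked lists (0.58, percentile 83.2) were inside the range of random lists. Highest were Mgp, Spp1, Cyp1b1 (7.94, probe sets 2.43 to 7.94), the acute-phase Serpina3n (7.83), Fxyd6 (7.69), Csf1r, Fosl1 (7.66, probe sets 1.90 to 7.66) and Lcn2. Lowest were Mup10 (-7.37), Vmn2r84 (-6.17), Prol1 (-5.97), Pramel34 (-5.83), Csn1s2a (-5.75), Orly (-5.28), Ncam2 (-5.17) and Gabra5 (-5.17). Mup10, Vmn2r84 and Pramel34 have near-identical copies, so the copy measured is uncertain.

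MC of biliary fibrosis, set against MC with no stated injury, had 1283 genes higher and 967 lower, with inflammatory genes among the highest. This pair crosses 3'/5' ratios of Gapdh of 2.01 and 13.79. Both counts were far smaller without genes 2-fold apart between sham PF and VitA-GFP+ cells, as given below. Chemokines and cytokines were higher by a median of 1.83 (percentile 100, 12 of 28, 0 lower): the serum amyloid Saa3 (7.76), Cxcl14 (5.29), Cxcl2 (4.44) and Lcn2 (4.17). Macrophage markers were higher by 1.94 (percentile 100, 9 of 18, C1qb 8.02, Ctss 4.26) and endothelial markers by 1.77 (percentile 100, 7 of 20 higher, 2 lower, Lyve1 3.09, probe sets -0.08 to 3.09, Kdr -3.08). Mesothelial markers had a median of -0.57 (percentile 0.395, 6 of 29 lower, 3 higher, Nkain4 -3.11, Cdh1 7.45), which became 2.40 when the difference between sham PF and VitA-GFP+ cells was subtracted. Their median level was 1.58 in sham PF and 4.97 in VitA-GFP+ cells, so the subtraction raises them by construction. In the same setting Nkain4 became 0.51, Kdr 1.63 and Id1 0.58. Portal fibroblast markers had a median of -0.51 (percentile 1.91, Ly6a 3.07, Fbln1 -2.78). Msln differed by -1.74, Wt1 by 0.49 and Gpm6a by -0.25. Msln was lower by more in sham PF than in VitA-GFP+ cells (-5.76), so the subtraction turns its sign.

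Myofibroblast activation genes in MC had a median of 0.22 (percentile 68.3), with 9 of 39 higher and 2 lower: the gelatinase Mmp2 (5.08), Col8a1 (4.98, probe sets -1.13 to 4.98), periostin, Postn (4.26) and Spp1 (3.72). Fibrillar collagens had a median of 0.24 (percentile 77.8, 3 of 31 higher: Postn, Thbs1 3.59 and Lum 2.13), Col1a1 differed by 0.09 (probe sets -1.45 to 0.09) and Acta2 by -0.48. With the difference between sham PF and VitA-GFP+ cells subtracted, the median was -0.78 for collagens and -0.48 for proteases. The other lists lay inside the range of random lists: smooth muscle 0.80 (percentile 95.8), hepatocyte 0.88 (percentile 97.0), lymphocyte, natural killer and neutrophil 0.64 (percentile 87.3), retinoid 0.57 (percentile 89.1), cholangiocyte 0.53 (percentile 83.1), epithelial junctions 0.51 (percentile 90.9), HSC markers 0.50 (percentile 89.2, Rgs5 8.29), cholesterol and fatty acid synthesis 0.46 (percentile 89.6), glycolysis 0.40 (percentile 89.1, Hk1 3.88), interferon response 0.36 (percentile 81.9), proteases 0.24 (percentile 52.9), transition regulators 0.17 (percentile 50.6, Id1 -3.80), proliferation 0.11 (percentile 32.9), immediate early -0.02 (percentile 49.7), basement membrane -0.09 (percentile 31.7) and sex-linked 0.70 (percentile 81.7).

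Rgs5, C1qb, the hyaluronidase Cemip (8.02), Sprr1a (8.01), Saa3, Shisa9 (7.49), Cdh1 and Serpina3n (7.44) were the highest differences in MC, and C79246 (-6.66), Orly (-6.60), Enpp2 (-5.88), Mup10 (-5.73), Xist (-5.57), C77815 (-5.36), Cd84 (-5.32) and Lrrc31 (-5.31) the lowest. Averaging a gene's probe sets left 848 genes higher. MC with no stated injury held both Xist (11.41) and Ddx3y (9.67). The strip plots of list members show these 3 fibrosis pairs on 1 scale, with a dot per gene, a bar at the list median and dotted lines at the 4-fold bounds.

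**Figure D2:**
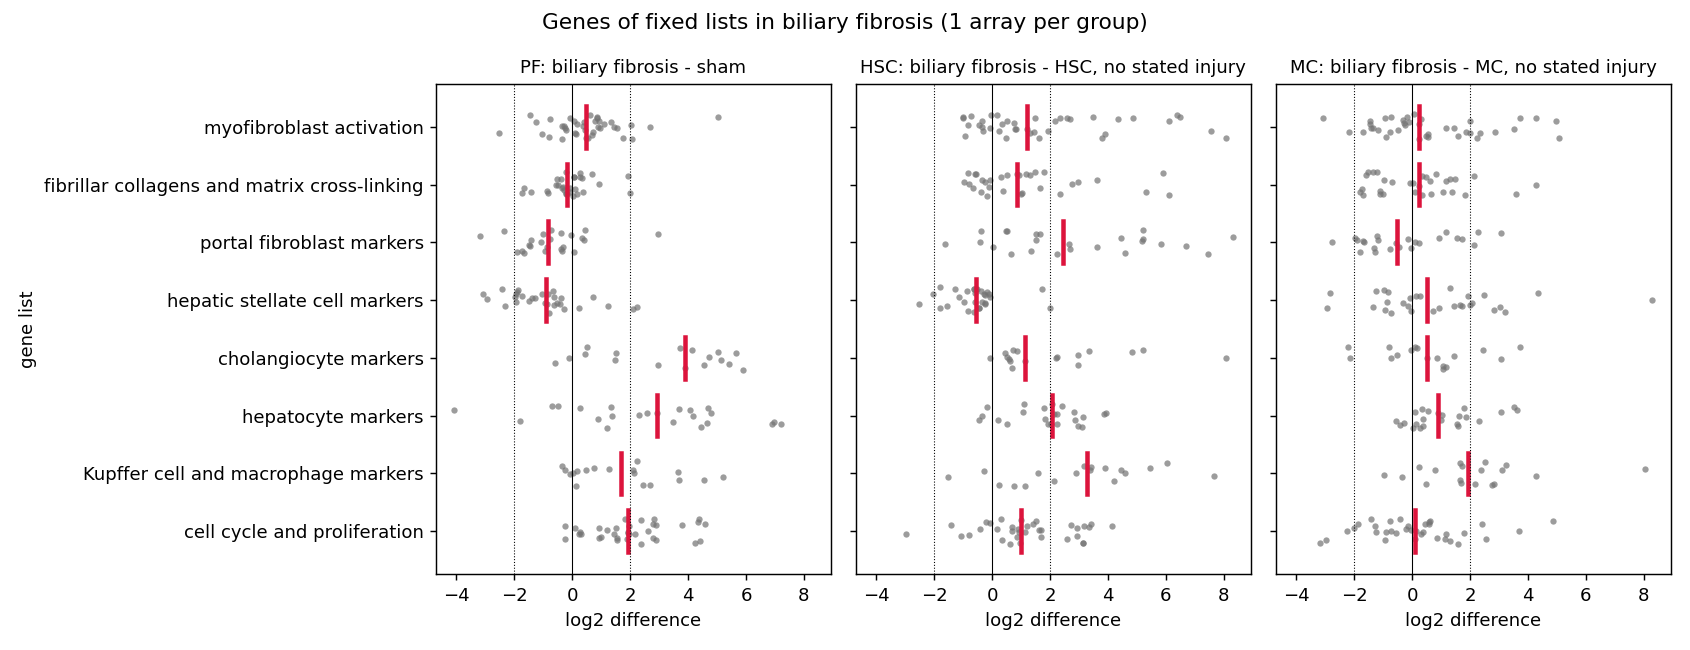
Log2 differences of the genes of 8 lists in PF, HSC and MC of biliary fibrosis. Each dot is a gene, with vertical jitter for visibility only, the red bar is the median of the list, the solid line is 0 and the dotted lines are the 4-fold bounds. Each difference is between 2 single arrays.

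The 3'/5' ratios of control probe sets, read here as RNA quality, differed between the arrays compared for HSC and MC. RNA was amplified before labelling, and what amplification adds to these ratios was not measured. The ratio of 3' over 5' probe sets for Gapdh was 1.42 to 2.01 in whole liver and the 3 fractions with no stated injury, 5.68 in HSC of biliary fibrosis, 10.16 in PF of biliary fibrosis, 13.22 in sham PF and 13.79 in MC of biliary fibrosis. The Actb ratio ran from 1.43 to 2.26 and from 4.45 to 5.98 in the same 2 sets of arrays, as the bars of these ratios show. The HSC and MC pairs cross these 2 sets and the PF pair does not. Sample codes form 3 series: 1 for the 4 arrays with high ratios, 1 for whole liver, HSC and MC with no stated injury, and 1 for the VitA-GFP+ array alone. The median SD between probe sets of 1 gene was 0.393 in the PF pair, 0.666 in the HSC pair and 0.935 in the MC pair. Without genes that were 2-fold apart between sham PF and VitA-GFP+ cells, which also differ in these ratios but cross another pair of code series, 550 genes were higher and 396 lower in HSC, and 694 higher and 536 lower in MC. With the 75th percentile as minimum level, 471 genes were higher in PF, 661 higher and 209 lower in HSC, and 843 higher and 527 lower in MC.

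**Figure D3:**
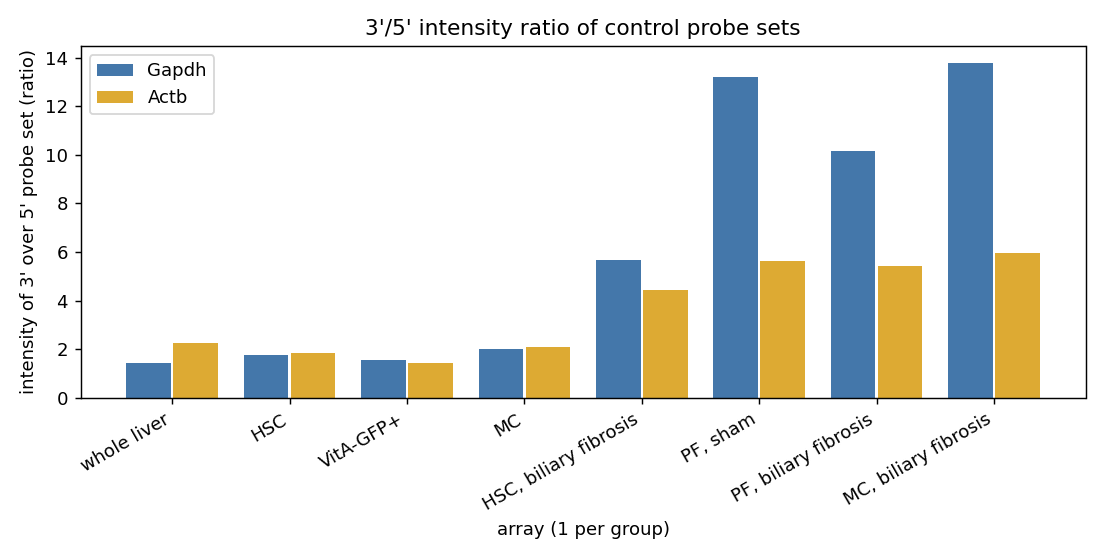
Ratio of the intensity of the 3' over the 5' control probe set for Gapdh and Actb on each array. A ratio near 1 means even signal along the transcript.

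Across the 3 fibrosis pairs, 85 genes were higher in all and 9 lower in all. Among the 85 were the epithelial Cdh1, Dsp and Prom1, the macrophage genes C1qb, Ctss, Lyz2 and Tyrobp, the hepatocyte gene Gc, and Lcn2, Saa3, Il1rn, Spp1 and S100a4. HSC and MC shared 379 higher genes (75.7 if independent) and 306 lower genes (30.3), with a correlation of 0.545 over all genes. PF and HSC shared 263 higher (46.0) and 20 lower (10.2), and PF and MC 154 higher (48.3) and 40 lower (15.2). The counts in parentheses take all 20677 genes as the base, though genes under the minimum level cannot be called. A base of genes that can be called would give larger counts, so the excess over them is overstated. Without genes 2-fold apart between sham PF and VitA-GFP+ cells, HSC and MC shared 132 higher and 165 lower genes, and 27 were higher and 2 lower in all 3 pairs. Subtraction of the difference between those 2 arrays went the other way, with more genes shared by PF and MC and by all 3 pairs.

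Cell identity genes also set the 3 fractions of biliary fibrosis apart. Against the higher of the other two fibrosis arrays, 279 genes were higher in HSC, 363 in PF and 317 in MC. HSC markers were higher in HSC by a median of 3.02 (percentile 100, 20 of 30), including Lrat (9.06, probe sets 5.78 to 9.06) and Reln (7.45), with Fcna (8.42), Orm1 (6.84) and the endothelial Plvap (5.998) beside them, and the retinoid list had a median of -0.19 (percentile 76.0, 4 of 22 higher). Mesothelial markers were higher in MC by 1.57 (percentile 100, 9 of 29), and the highest there were Abcg5 (6.52), Chst4 (5.74), Slc23a3 (5.73), Prph (5.31, probe sets 1.85 to 5.31) and Rbfox1 (5.05). PF had portal fibroblast markers higher by 0.51 (percentile 100, 2 of 24) and cholangiocyte markers by 0.92 (percentile 100, 7 of 17). Highest in PF were Ighg (7.69, probe sets 1.17 to 7.69), Ighg3 (6.47, probe sets -0.37 to 6.47), the B cell gene Pou2af1 (6.18), Kcnma1 (5.89) and Corin (5.63). The count in PF was 238 with probe sets averaged and 241 with the 75th percentile as minimum level.

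Genes often used to tell these cells apart differed as follows in PF, HSC and MC of biliary fibrosis. Entpd2 of portal fibroblasts gave -1.08, 0.02 and -1.96, and Thy1 gave -0.40, 4.58 and 2.29. Gpm6a gave 3.48, -0.76 and -0.25, Msln 3.31, 0.93 and -1.74, and Wt1 0.34, 5.84 and 0.49. Acta2 and Col1a1, both linked with myofibroblasts, gave 1.46, 4.34 and -0.48, and 0.27, 1.78 and 0.09. Lrat gave -3.06, -0.58 and -0.09.

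Sham PF and VitA-GFP+ cells, both with portal fibroblast genes and neither with biliary fibrosis, also differed in markers of other cells. In sham PF 407 genes were higher and 794 lower. Portal fibroblast markers had a median of 0.24 (percentile 84.4, 4 of 24 higher, 1 lower, Slit2 2.62, Ptgds -4.28). Endothelial markers had a median of -4.31 (18 of 20 lower, Emcn -5.99), macrophage markers -3.70 (14 of 18, C1qb -5.60), mesothelial -2.89 (17 of 29, Krt19 -5.95, Slpi -5.86), hepatocyte -2.48 (11 of 23, Serpina1c -5.32) and smooth muscle -2.25 (10 of 19, Myl9 -4.80), each at percentile 0. Xist (7.49), Pm20d1 (6.43), Foxl2os (5.69), Pcdh8 (5.62) and Cxcl5 (5.46) were highest and Ddx3y (-7.70, probe sets -7.70 to -4.66), Myl7 (-7.09), Gpihbp1 (-6.70), Plet1 (-6.47) and Chst4 (-6.36) lowest. The count of higher genes was 242 with probe sets averaged, and that of lower genes 471 at the 75th percentile. The labels name no gate for PF, and this pair crosses the 2 sets of arrays with different 3'/5' ratios and differs in sex-linked transcripts.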

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

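The tests of the epithelial genes in PF, with the bounds and rules that decide them, were chosen only after the result was seen. Those of the genes shared by HSC and MC were written before. An earlier test of hepatocyte RNA, a log2 gap of 2.06 between the share its markers need and the one the 5 brightest give, with an SD of 1.78 over 14 genes, was first read as excluding it and then as deciding nothing, and was replaced once its value was known.

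The first pattern is the 306 genes 4-fold lower in both HSC and MC of biliary fibrosis. Of these, 40.52% were at least 2-fold lower in sham PF than in VitA-GFP+ cells, a pair that crosses from low to high 3'/5' ratios without biliary fibrosis, against 10.13% to 17.65% in random lists, and 60.14% among the 138 genes above the array median there. In the PF pair, which stays within 1 series of sample codes, 15.36% were at least 2-fold lower, against 4.90% to 10.46%, and 30.10% among the 103 genes above the array median there. Both shares are above random lists and under the 50% that either explanation called for, sham PF is part of both pairs, and the VitA-GFP+ array has a code series of its own, so its pair is not shown to cross what the HSC and MC pairs cross. A second round of arrays with other RNA quality and an effect of biliary fibrosis on all fractions cannot be told apart, since the HSC and MC arrays of biliary fibrosis belong to 1 code series and those without it to another.

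The second pattern is the 379 genes 4-fold higher in both. Here 37.99% were at least 2-fold higher in sham PF than in VitA-GFP+ cells (random lists 10.55% to 17.41%), but 27.18% were at least 2-fold lower there. In the PF pair 41.16% were at least 2-fold higher (random lists 8.97% to 15.30%) and 8.71% lower. A difference between rounds and biliary fibrosis could each account for part, and again cannot be told apart by this design.

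The third pattern is 40 hepatocyte, cholangiocyte and epithelial junction genes 4-fold higher in PF of biliary fibrosis than in sham PF. RNA of mesothelial cells as the sole origin of all 40 is argued against, since 75% of them were at least 2-fold higher in PF than in MC of biliary fibrosis itself. The 40 were chosen as high in PF and include 14 hepatocyte markers. Each of these 14 was at least 2-fold higher in PF than in MC, which raises the 75%. Of the 40 genes, 85% were higher in PF at all. Those not higher were Krt7 (10.12 in PF, 11.88 in MC), Krt19 (10.22 and 11.07), Cdh1 (11.44 and 11.77), F11r (9.68 and 10.49), Perp (10.34 and 10.91) and Pkp2 (10.48 and 12.05). All of these are cholangiocyte or junction genes. Krt18, Krt8, Dsg2 and Cftr were higher in PF by under 2-fold. Mesothelial RNA for part of the pattern stays open. For the 26 cholangiocyte and junction genes, RNA with the make-up of the whole-liver array, which had no stated injury, is argued against. Of these, 73.08% (19) were at least 2-fold higher in PF than there. For the 14 hepatocyte markers, 154 genes abundant in whole liver were set against the level that a share of its RNA brings. At 1.19%, the lowest share any of these 14 needs, 29.22% stayed at least 4-fold below that level, and 57.14% at their median share of 4.96%. The other members of the hepatocyte list, not called, all gave lower shares, such as Hpd (0.10%) and Apoa1 (0.11%). The 14 were thus chosen for high shares, which makes a shortfall of the 154 genes more likely. The binomial interval of 22.61% to 36.84% treats genes as independent, though they vary together. HSC of biliary fibrosis gave 5.19% and 41.56%, but at the lowest and median shares of its own markers, so the arrays are not compared at 1 share. These values argue against RNA with the make-up of the whole-liver array. What RNA quality adds to the shortfall (Gapdh ratios 1.42 in whole liver, 10.16 in PF) was not tested. RNA of cholangiocytes stays open and was not tested, since no array holds cholangiocytes alone and their markers define the pattern, and so do hepatocytes with another make-up in biliary fibrosis. Portal fibroblasts that take up epithelial genes cannot be told apart from these by portal fibroblast markers, which differed by a median of -0.82, and the sex of the mice, which differs by transcript between the 2 arrays, was not tested.

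Genes that went 4-fold in opposite directions in 2 fibrosis pairs were noted as differences between groups, which were not tested. PF and HSC had 13 genes higher in PF and lower in HSC and 27 the other way (Col4a4 -2.48 and 4.70). PF and MC had 40 higher in PF and lower in MC (Mki67 4.60 and -2.25, Krt19 3.74 and -2.22, the latter 3.73 after the subtraction of the difference between sham PF and VitA-GFP+ cells) and 23 the other way (Cxcl12 -2.18 and 3.26). Mki67 differed by -1.86 between those 2 arrays, so after the subtraction it no longer meets the 4-fold rule in MC. HSC and MC had 25 higher in HSC and lower in MC (Fbln1 2.64 and -2.78) and 7 the other way (Ntn1 -2.03 and 2.82). The genes in parentheses are list members picked after their values were seen.

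Probe sets that name no gene or several lie outside the gene counts. Of these 7026, 241 passed the 4-fold rule in PF, 899 in HSC and 1183 in MC of biliary fibrosis, each against the same array as the genes were.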

How the results depend on the processing

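The swaps of sham PF and VitA-GFP+ cells and the removal of genes that set them apart were chosen after seeing the data, the others before. The 17 counts of the comparisons, and 11 more for genes lower than in whole liver or shared by fibrosis pairs, all stayed within 1.5 times under quantile normalization, the shift to the same median, no minimum level and the removal of probe sets that match several transcripts. Under the subtraction 4 of 4 and 3 of 8 did. Of 1519 list medians recomputed, 1366 stayed within 0.5, 138 moved by more and 15, from lists outside the range of random lists, changed sign. Of medians inside that range 62 changed sign too, 12 of them with a move of more than 0.5. Of 2484 values of single genes 2050 stayed, 411 moved and 23 that met the 4-fold rule changed sign, as did 25 of the others. Array medians lay between 5.31 and 5.68, so the shift to the same median could move no difference past 0.5. Its 573 gene values stayed by construction and enlarge the count that stayed. Under the subtraction 43 gene values stayed, 154 moved and 14 that met the 4-fold rule changed sign. For list medians there, 16 stayed, 28 moved and 2 changed sign. What signal over background limits was not measured beyond the minimum levels tried. Values from the other deposited table were not run, since the tables are the same, and lists with under 5 members above the 75th percentile have no value there. Where no cause follows from the construction of an alternative, the cause was not tested. No paired analysis was possible because each group has 1 array.

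The 2-fold rule, looser by construction, gave 749, 1475 and 823 genes for HSC, VitA-GFP+ cells and MC against the other fractions, and 3320, 3661 and 3329 higher and 4219, 3315 and 4595 lower than in whole liver. It gave 1908 higher and 1397 lower in PF, 3093 and 1832 in HSC, and 3552 and 2673 in MC of biliary fibrosis. Among the fibrosis fractions it gave 1101, 1066 and 1321 for HSC, PF and MC, and 1891 higher and 2469 lower in sham PF than in VitA-GFP+ cells. The 75th percentile as minimum level, stricter by construction, gave 369 for VitA-GFP+ cells, 471 higher in PF, 661 higher and 209 lower in HSC, 843 and 527 in MC, 241 for fibrosis PF and 471 lower in sham PF. With probe sets averaged, 848 genes were higher in MC of biliary fibrosis, 238 in fibrosis PF and 242 in sham PF. VitA-GFP+ cells in place of sham PF gave 810 genes lower in PF (104 shared), and sham PF in place of VitA-GFP+ cells 397 for MC (165 shared). Without genes 2-fold apart between those arrays, 550 were higher and 396 lower in HSC, and 694 and 536 in MC.

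Genes shared by HSC and MC of biliary fibrosis, by PF and HSC, by PF and MC and by all 3 numbered 1461, 774, 599 and 360 higher and 1031, 235, 324 and 132 lower under the 2-fold rule. At the 75th percentile they numbered 207, 99, 75 and 35 higher and 104, 7, 17 and 2 lower, and without genes 2-fold apart between sham PF and VitA-GFP+ cells 132, 90, 69 and 27 higher and 165, 5, 16 and 2 lower. With probe sets averaged, HSC and MC shared 238 higher and PF and HSC 13 lower genes. After the subtraction PF and MC shared 283 higher and 85 lower, PF and HSC 62 lower, and all 3 had 195 higher and 34 lower.

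The shift to the same median moved the median of all genes from 0.25 to 0.42 in MC of biliary fibrosis, from 0.17 to 0.40 in sham PF against VitA-GFP+ cells, and against whole liver from -0.20 to -0.57 in VitA-GFP+ cells, -0.04 to -0.26 in MC and -0.06 to -0.22 in HSC. The share of higher among called genes went from 33.9% to 48.2% in sham PF and from 59.0% to 47.0% in VitA-GFP+ cells against whole liver.

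Subtraction of the difference between sham PF and VitA-GFP+ cells assumes the same kind of cell in both and the same difference between sets of arrays as in HSC and MC, though the VitA-GFP+ array has a sample code of its own series. Their markers of other cells differ, so those lists move by construction. In HSC of biliary fibrosis the medians became 6.35 for macrophage, 5.19 endothelial, 4.67 mesothelial, 4.44 hepatocyte, 3.65 sex-linked, 3.60 epithelial junction, 3.38 lymphocyte and 3.28 cholangiocyte genes. They became 2.21 for smooth muscle, 1.501 glycolysis, 0.97 proteases, 0.75 retinoid, 0.21 collagens, 0.13 chemokines and -0.18 interferon response, and HSC markers changed sign to 0.17. In MC they became 5.88 for endothelial, 5.08 macrophage, 4.79 sex-linked, 3.21 lymphocyte, 2.69 epithelial junction, 2.66 cholangiocyte, 2.62 hepatocyte and 2.45 smooth muscle genes. They became 1.497 for HSC markers, 1.13 glycolysis and 0.91 interferon response, and changed sign to -0.48 for proteases, -0.78 for collagens and 2.40 for mesothelial markers. Single genes that met the 4-fold rule and changed sign were Esam (3.22), Id1 (1.81), Xaf1 (0.105) and Cxcl5 (-0.25) in HSC. In MC they were Krt19 (3.73), Myl9 (1.74), Kdr (1.63), Cldn15 (1.61), Bst2 (1.11), Fdps (0.82), Id1 (0.58), Nkain4 (0.51), Xaf1 (0.16) and Hk2 (-0.014).

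At the 75th percentile, fewer list members count. In PF of biliary fibrosis the medians were then 4.54 for cholangiocyte, 4.43 hepatocyte, 3.04 mesothelial and -1.44 endothelial markers. In HSC they were 6.003 for mesothelial, 5.18 portal fibroblast, 4.83 cholangiocyte, 4.58 macrophage and 2.42 epithelial junction genes, with a change of sign for endothelial markers (-0.53). In MC they were 1.98 for proliferation and -1.25 for portal fibroblast genes, with a change of sign for epithelial junctions (-0.009), proteases (-0.30), cholangiocyte markers (-0.52), collagens (-0.52) and HSC markers (-0.74). Among fractions they were 0.90 for retinoid genes in HSC, 4.21 for macrophage and 4.50 for lymphocyte markers in VitA-GFP+ cells, with a change of sign there for chemokines (-0.17), cholangiocyte markers (-0.11) and epithelial junctions (-0.67). Collagens against whole liver were at 4.17 in HSC and 4.36 in MC, and proliferation in VitA-GFP+ cells changed sign to 0.53. Sham PF against VitA-GFP+ cells gave -4.26 for macrophage, -3.44 mesothelial and -3.11 hepatocyte markers. Among fibrosis fractions retinoid genes in HSC changed sign to 0.84 and collagens in PF to -0.072.

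With probe sets averaged, proliferation was at 1.30 and sex-linked genes at 3.12 in PF, HSC markers, with a change of sign, at -0.054 and lymphocyte markers at 1.33 in MC, HSC markers at 2.36 in fibrosis HSC, hepatocyte markers at -1.75 and mesothelial markers at -2.01 in sham PF, and portal fibroblast markers at -4.75 in HSC against the other fractions and 3.38 in VitA-GFP+ cells against whole liver. Near 0, the sign changed in fibrosis PF for collagens (-0.17), cholesterol synthesis (-0.072) and myofibroblast genes (-0.064), and in fibrosis MC for interferon response (-0.073). Fdps changed to 0.29 in MC of biliary fibrosis. After the shift to the same median it changed for collagens in fibrosis PF (-0.089) and for immediate early and myofibroblast genes in VitA-GFP+ cells against the other fractions (-0.090 each). Without probe sets that match several transcripts it changed for collagens in fibrosis PF (-0.083), Hnf4a (-0.011) and Pm20d1 (0.98) in PF for Hnf4a in HSC (-0.106), for Cdca8 (0.94), Smad7 (-0.44), Ttr (-0.70) and Fdft1 (-1.42) in MC of biliary fibrosis, and for Acta2 in MC against whole liver (-0.35), and mesothelial markers in sham PF were at -3.44.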

Other observations

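Arrays of the same sort were not always the closest over the whole array. Over 15606 genes the correlation of log2 levels was 0.894 between the 2 PF arrays, 0.886 between sham PF and VitA-GFP+ cells, 0.847 between the 2 HSC arrays and 0.821 between the 2 MC arrays. HSC of biliary fibrosis correlated with sham PF at 0.886, with PF of biliary fibrosis at 0.883 and with VitA-GFP+ cells, of another series of sample codes, at 0.876. MC of biliary fibrosis correlated with PF of biliary fibrosis at 0.848 and with sham PF at 0.823, and MC with no stated injury with VitA-GFP+ cells at 0.821.

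Sex-linked transcripts divided the arrays by neither sort nor injury. Xist was at 11.40 in whole liver, 11.41 in MC and 11.96 in sham PF on the log2 scale, and at 4.37 to 5.84 in the other 5 arrays. Ddx3y was at 2.04 in whole liver and 2.78 in sham PF, and at 9.67 to 11.83 elsewhere. MC with no stated injury had both.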
